A study of Mus musculus with 18 samples.

How the data were processed

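Nascent RNA was measured in mouse embryonic stem cells of the E14tg2a line, of 129SV background. In these cells Med24, a subunit of the Mediator complex that links transcription factors to RNA polymerase II, had been knocked out and its function was replaced by a FLAG-Med24 cDNA under a tetracycline-regulated promoter. The cells also carried cRAF-ErT2, a kinase fused to a modified estrogen receptor domain that 4-hydroxytamoxifen (4OHT) switches on, so that 4OHT activates the ERK pathway. Cells given doxycycline at 500 nM (labelled WT, called rescued here) expressed the cDNA, and cells without it (labelled KO, called knockout here) did not; both were kept so for several passages. Per the labels' protocols, cells were grown in serum with LIF and Chir99021, a GSK3 inhibitor, at 2 µM, moved for 24 h into serum and LIF with the FGF receptor inhibitor PD173074 at 250 nM, and then left untreated or given 250 nM 4OHT. New RNA was labelled for 15 min with 5 mM ethynyl uridine, captured by click chemistry and made into libraries with an NEBNext Ultra II kit.

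The deposited table held whole-number read counts per gene, not normalized, for 25897 gene symbols, and the authors' values were used as deposited. The submitters' processing notes name STAR, featureCounts, DESeq and the mm10 genome. Tool versions, the annotation release, whether reads were counted by strand and whether introns were counted are not given in the sources used here. Reads from a gene and from an overlapping or antisense gene can therefore not be told apart. Mitochondrially encoded genes were listed at 0 counts in all 18 libraries (13 of 13), so that list was not tested. Positions come from GENCODE release M21 of GRCm38, the assembly that mm10 denotes, which held 98.7% of the symbols.

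There were 6 groups of 3 libraries: rescued and knockout cells at 0, 2 and 8 h of 4OHT. Each group held the clones A, B and C. The P values therefore measure the spread between clones labelled alike. Library totals ranged from 6691177 to 14541145 counts, at which 3 counts, the number that a count of 0 still allows, correspond to between 0.196 and 0.629 CPM. Counting intervals and floors cover counting error only, since reads carry no molecular identifiers. Chi-square comparisons found no pair of replicates that agreed within sampling noise. Doxycycline was given to all rescued and to no knockout libraries, so its own effects cannot be separated from those of Med24. The labels name no spike-in, so all changes are relative to the other genes of a library.

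Counts were analysed with edgeR 4.0.16 in R 4.3.3. A total of 14128 genes passed filterByExpr. Libraries were scaled by TMM and fitted in one quasi-likelihood model with 6 group means, and 9 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. CPM values are edgeR's library-scaled counts after TMM, given as mean ± SD, and log2 fold changes are given ± SE. Where a group had no counts, the fold is a lower bound against 3 counts over the whole group, and with 1 to 3 counts in a group it is a ratio of summed counts with an exact 95% counting interval. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over 207 tests. Where no count adjusted over the list alone is given beside a list, it was the same as that over all genes tested. The retained response is the slope through the origin of the knockout on the rescued log2 fold change, over genes called for the average of both responses.

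The groups, tests, 24 gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Med24 first. In each comparison it then took genes with an adjusted P under 0.05 and a mean of at least 5 CPM. Outside the interactions it also required no overlap between groups (10% of genes by chance). Among these genes it named the 8 highest and 8 lowest log2 fold changes, or 5 and 5 for interactions. It passed over predicted gene models. Last came up to 4 members of each list with the smallest P, and all members of the immediate early, ERK feedback, naive pluripotency and primitive endoderm lists. The lists covered immediate early, ERK feedback and ETS-factor, naive, general, formative and primed pluripotency, primitive endoderm, gastrulation and mesoderm, trophectoderm, neural, fibroblast, 2-cell-like, Mediator, cholesterol synthesis, p53 target, heat shock, integrated stress response, Wnt target, BMP and Nodal target, ribosome biogenesis, cell cycle, MRTF and SRF cytoskeletal, ribosomal protein, mitochondrially encoded and histone genes.

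The clone letters A, B and C recur in every group, but the labels tie no letter to a batch or day. The deviations of same-letter libraries from their group means had a mean correlation of 0.016 across genes (range -0.10 to 0.083), and 12 of 18 libraries correlated best with their own letter. Letters assigned at random would on average give fewer such libraries, so a weak pairing by clone remains possible. The fit with a replicate block was an alternative, and it called 1831 genes for the 2 h interaction against 1866 without it. The other alternatives were RLE scaling, library size alone, no filter on low counts, DESeq2 1.42.0, fits on only the groups compared, a 2-fold threshold, and each library left out in turn.

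The procedure was tested on simulated counts with the real means, library sizes and dispersions. Of genes changed 2-fold, 85.4% were recovered in the comparison of 2 h with 0 h in rescued cells (13855 genes tested, 10 false calls), and 68.8% in the 2 h interaction (3 false calls). At 1.5-fold the shares were 74% and 52%. At 1.25-fold they were 28% and 14%. No more than 50 genes were changed at each fold, far fewer than were called in the real data. Benjamini-Hochberg adjustment is stricter when few genes change, so these shares need not hold for the real comparisons. A simulated slope of 1 was returned as 0.969 and one of 0.8 as 0.774, so noise pulls the 2 h slope down. The simulated responses were the estimated 2 h fold changes of rescued cells, which already hold noise, so the real pull may be larger. The 8 h slope was not simulated.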

Results

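Newly made RNA was counted in 18 libraries of mouse embryonic stem cells, 3 for each of 6 groups. Rescued cells, with Med24 expressed from a doxycycline-driven cDNA, and knockout cells, without it, were compared before and at 2 h and 8 h after 4OHT switched on cRAF and thereby ERK signalling. Library totals lay between 6691177 counts (knockout, 8 h, clone C) and 14541145 (rescued, 8 h, clone A). The first principal component held 45.8% of the variance and parted 0 h from the later times. The third held 7.73% and parted knockout from rescued libraries.

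Med24 (GRCm38 chromosome 11, 98704591 to 98729435, minus strand) was lower in every knockout library. At 0 h it stood at 39.5, 41.7 and 35.5 CPM in knockout clones A, B and C and at 528, 602 and 515 CPM in rescued clones. The log2 fold change was -3.81 ± 0.081 at 0 h, -5.14 ± 0.083 at 2 h and -3.35 ± 0.084 at 8 h (n = 3 per group). In rescued cells Med24 reads rose 2.98-fold at 2 h, from 548 ± 47 to 1630 ± 130 CPM, and stood at 404 ± 4.0 CPM at 8 h. Reads of the cDNA and of the endogenous locus were counted together.

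**Figure D1:**
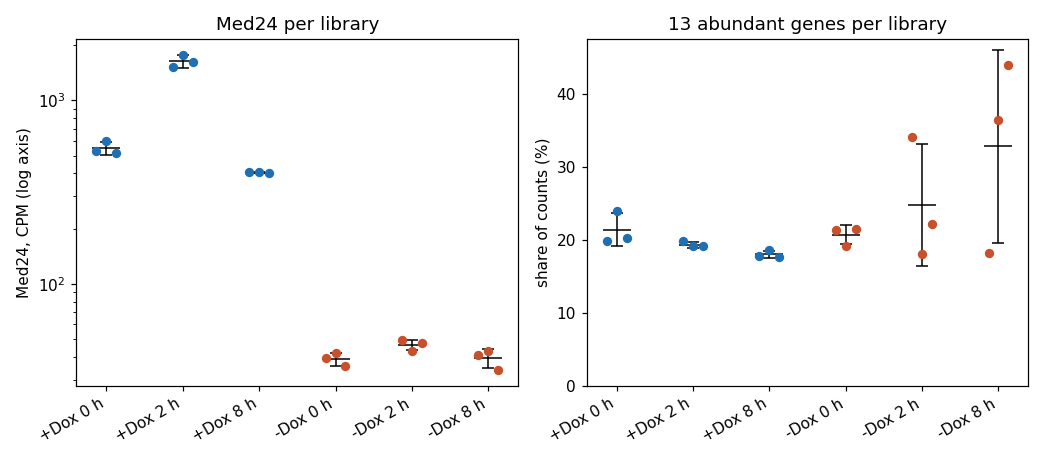
Med24 in CPM on a log axis (left) and the share of counts in 13 abundant genes in percent (right), by group, with one point per library and the mean ± SD of 3 libraries as bars. Knockout libraries lie near 40 CPM of Med24, and 3 knockout libraries hold 34.2%, 36.4% and 44.0% of their counts in the 13 genes.

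A set of 13 abundant genes, led by Cdk8 and Lars2, held 17.7% to 24.0% of counts in 15 libraries. In knockout cells they held 34.2% at 2 h in clone A, 36.4% at 8 h in clone B and 44.0% at 8 h in clone C. They include Jarid2, Cd44, Kpna1 and Fgfr2. They were chosen by a mean above 1000 CPM and, within groups, a correlation with Cdk8 above 0.9 and a log2 SD above 0.3. That they moved together between clones of one group was therefore fixed by the choice. Some results are also given without these 3 libraries, an alternative chosen after seeing the data. It leaves only clone A in the knockout 8 h group, so its 8 h knockout values rest on a single library.

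The first comparison asked how nascent transcription in rescued cells answered 2 h of ERK activation. Immediate early genes, which respond first to a signal and many of which encode transcription factors, rose together: 27 of 28 measured members were higher and 1, Nr4a2, was lower, also when adjusted over the list alone. Egr1 rose from 44.6 to 3525 CPM (log2 fold change 6.31 ± 0.12), Arc by 6.17 and Fosl2 by 5.65 on the log2 scale. Egr3 (chromosome 14, 70077203 to 70082614) had no counts at 0 h and 194 ± 11 CPM at 2 h, at least 1520-fold higher. ERK feedback and ETS-factor genes, called feedback genes here, were higher in 18 of 21 and lower in 1. They include genes of phosphatases and Sprouty proteins that restrain the pathway, and of ETS transcription factors. Among them Phlda1 rose by 6.28, Dusp5 by 4.37 and Spry4 by 4.29 on the log2 scale, and Dusp2, with 3 counts at 0 h, was 289-fold higher (95% counting interval 98.5 to 1400).

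Naive pluripotency genes fell: 15 of 20 were lower and 2, Klf5 and Socs3, higher (2 higher and 16 lower when adjusted over the list alone). Nanog (chromosome 6, 122707489 to 122714633) fell by 2.08 ± 0.079 on the log2 scale from 330 CPM, Klf2 fell by 2.38, Prdm14 fell by 2.79 and Esrrb fell by 1.77. Camera gave adjusted p values of 1.19e-36 for immediate early, 1.71e-35 for feedback and 3.1e-07 for naive genes, and with an estimated correlation 0.00295, 0.000191 and 0.0324. Cholesterol synthesis genes were higher in 17 of 19 (camera adjusted p 3.17e-06, adjusted p = 0.334 with an estimated correlation).

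Besides these lists, the largest rises at 2 h were in Rrad, a small GTPase gene with 1 count at 0 h (915-fold, counting interval 164 to 36200), Lor, which encodes loricrin (7.60 ± 0.24), Iqsec3 (6.83), Gpr142 (6.82), Sox8 (6.54) and Krtdap (6.46 on the log2 scale). The largest falls were in Slc5a11 (-4.42 ± 0.22), the Nodal antagonist gene Lefty1 (-3.97), Prmt8 (-3.85), Fgf10 (-3.81), Plpp3 (-3.72), Pgpep1l (-3.70), Foxi3 (-3.67) and Trim67 (-3.57). Lefty1 and Lefty2 are close copies whose reads the counting could split, so values of both are uncertain. Prmt8 moved with Cdk8, one of the 13 abundant genes, between libraries of one group. In total edgeR called 9354 of 14128 genes, 4574 higher and 4780 lower (48.9% higher, 31.9% with library size alone).

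At 8 h in rescued cells, feedback genes were still higher and naive genes lower, now beside genes of later cell states. Feedback genes were higher in 19 of 21 with none called lower (1 lower when adjusted over the list alone; camera adjusted p 6.58e-42, adjusted p = 0.000191 with an estimated correlation), with Dusp4 at 4.09, Dusp6 at 3.25 and Etv4 at 3.89 on the log2 scale. Immediate early genes were higher in 23 of 28 and lower in 3 (adjusted p = 0.0247 with an estimated correlation). Naive genes were lower in 15 of 20 and higher in 4, or 5 when adjusted over the list alone: Nanog fell by 4.06 ± 0.092, Prdm14 fell by 3.74 and Klf4 fell by 3.02, while Gbx2 was 2.65 higher. Formative and primed epiblast genes were higher in 8 of 15 and lower in 3 (adjusted p 3.02e-05, and 0.0417 with an estimated correlation), with Pou3f1 up by 3.70 ± 0.19, Cdh2 by 3.18 and Grhl2 by 2.55. Trophectoderm genes were higher in 8 of 10, among them Tead4 (3.13) and Cdx2 (3.54), though their camera adjusted p of 0.00599 became an adjusted p = 0.256 with an estimated correlation.

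Ccl20, a chemokine gene, had no counts at 0 h and was at least 220-fold higher at 8 h, and Egr3 at least 285-fold. Aldh1a3, which makes retinoic acid, rose by 8.42 ± 0.22 and Cyp26a1, which degrades it, by 6.25 ± 0.28 on the log2 scale. Grm6 (7.32), Gpr142 (6.95), Pou4f2 (6.20) and Npy (6.13) completed the highest 8. Among the lowest were Lefty1 (-7.96 ± 0.38), Prmt8 (-6.31), Cyp1b1 (-6.04), Hhip (-6.00), Mcf2 (-4.98), Lefty2 (-4.53) and Aqp3 (-4.48). edgeR called 4331 genes higher and 4417 lower.

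The same steps were then examined without Med24. At 2 h in knockout cells, immediate early genes were higher in 23 of 28 and lower in 2 (camera adjusted p 9.26e-25, adjusted p = 0.0108 with an estimated correlation), and feedback genes higher in 18 of 21 and lower in 2 (adjusted p = 0.00177 with an estimated correlation). Egr1 rose from 16.5 ± 1.5 to 2610 ± 78 CPM (log2 fold change 7.31 ± 0.13), Jun by 3.59 and Nptx1, a neuronal pentraxin gene, by 7.27. Egr3 was 2060-fold higher (counting interval 369 to 81200, 1 count at 0 h) and Lor 709-fold (196 to 5860). Rrad (7.46), Iqsec3 (7.16), Dusp2 (6.15) and Sec14l3 (6.14) were also among the highest 8. Naive genes were lower in 12 of 20 and higher in 6, with a camera adjusted p of 0.00759 and an adjusted p = 0.277 with an estimated correlation. Fgf10 (-3.95 ± 0.23), Prmt8 (-3.53), Foxi3 (-3.43), Plpp3 (-3.37), Rab3il1 (-3.34), Slc5a11 (-3.33), Pgpep1l (-3.21) and Fam13c (-3.13) fell most. edgeR called 4446 genes higher and 4968 lower (47.2% higher, 21.2% with library size alone).

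At 8 h in knockout cells, feedback genes were higher in 17 of 21 and lower in 1 (adjusted p = 0.00029 with an estimated correlation), immediate early genes higher in 19 of 28 and lower in 4 (adjusted over the list alone, feedback genes higher in 18 and immediate early genes lower in 5; adjusted p = 0.0595 with an estimated correlation), and naive genes lower in 13 of 20 and higher in 7 (adjusted p = 0.15 with an estimated correlation). Formative genes were higher in 9 of 15 and lower in 4 (adjusted p = 0.0323 with an estimated correlation). Ccl20 was at least 127-fold and Grm6 at least 92.5-fold higher, both from no counts, and Egr3 464-fold (counting interval 82.8 to 18400). Col6a5 (6.02 ± 0.31), Egr1 (5.91), Pla2g7 (5.76), Aldh1a3 (5.73) and Btbd17 (5.35) followed. Prmt8 (-6.31 ± 0.23), Lefty1 (-5.86), Cyp1b1 (-5.37), Trim67 (-4.12), Sirpa (-4.05) and Pknox2 (-3.99) were among those that fell most, with Rab3il1 also among the lowest 8. edgeR called 3990 genes higher and 4180 lower (48.8% higher, 14.7% with library size alone).

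Before ERK activation, part of the primitive endoderm genes, markers of the extraembryonic layer that forms beside the epiblast, stood higher in knockout cells. Doxycycline differed between the groups as well, so the difference cannot be assigned to Med24 alone. At 0 h 8 of 15 were higher in knockout cells and none was called lower (1 was lower when adjusted over the list alone). Gata6 was 2.50-fold higher (8.11 ± 0.42 against 3.23 ± 0.16 CPM), Gata4 2.31-fold (10.2 ± 0.87 against 4.36 ± 0.40 CPM), and Pdgfra, Col4a1 and Dab2 were higher by 1.72, 0.94 and 0.71 on the log2 scale. The list had a camera adjusted p of 1.4e-07, which became an adjusted p = 0.11 with an estimated correlation. Naive genes were lower in 8 of 20 and higher in 1 (10 and 1 when adjusted over the list alone), with Klf4 at -0.81 ± 0.081 and Nanog, which did not pass the test, at 0.12 ± 0.071 (adjusted p = 0.166 with an estimated correlation). Immediate early genes were higher in 3 of 28 (Atf3 at 2.43 ± 0.28, Fosl2 and Cyr61) and lower in 1, Egr1 (-1.44 ± 0.13). Feedback genes were higher in 3 of 21, with Dusp4 at 0.74, and lower in 3, with Spry4 at -1.07 (5 and 4 when adjusted over the list alone).

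Among genes of at least 5 CPM, the largest log2 differences at 0 h besides Med24 were in genes lower in knockout cells. Duox1 (chromosome 2, 122315672 to 122347972), a dual oxidase gene, fell from 41.3 ± 3.7 CPM in rescued to 2.79 ± 0.77 CPM in knockout cells, 14.9-fold, and Rapgef4 (chromosome 2, 71981240 to 72257474), an exchange factor for Rap activated by cAMP, was 5.80-fold lower. Msc (-2.04 ± 0.20), Ccdc141 (-1.95), Shf (-1.83), Hhip (-1.60) and Plxna4 (-1.60) followed. Shf (chromosome 2, 122348892 to 122369162) lies beside Duox1 on the opposite strand. Whether reads were counted by strand is not given, so the falls of Shf and Duox1 may not be separate. Among the higher were Rpl39l (1.73 ± 0.14, uncertain because of close ribosomal protein copies), Sspo (1.52), Tmem40 (1.34), Galnt6 (1.28) and Slc1a1 (1.23). Ribosomal protein genes were higher in 56 of 82 by a median of 0.25 on the log2 scale (70 of 82 when adjusted over the list alone, adjusted p = 0.173 with an estimated correlation), and histone genes, near-identical copies and so uncertain, were lower in 16 of 56 (21 when adjusted over the list alone, adjusted p = 0.636 with an estimated correlation). edgeR called 962 genes higher and 1362 lower (41.4% higher), of which 101 and 65 differed by more than 2-fold. With library size alone it called 213 higher and 207 lower (50.7% higher).

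At 2 h of 4OHT most members of the immediate early and feedback lists stood lower in knockout cells, relative to the other genes of a library. Immediate early genes were lower in 18 of 28 and higher in 2, and feedback genes lower in 13 of 21 with none called higher (20 and 4, and 13 and 2, when adjusted over the list alone). Fosl2 (log2 fold change -1.54 ± 0.072), Junb (-1.32), Phlda1 (-1.91) and Dusp5 (-1.57) were lower, whereas Jun was higher by 1.57 ± 0.065. Trophectoderm genes were lower in 7 of 10, with Tead4 at 82.2 ± 11 against 310 ± 8.0 CPM. The adjusted p values with an estimated correlation were 0.018, 0.00127 and 0.0417. Naive genes were higher in 11 of 20 and lower in 2, with Nanog higher by 0.81 ± 0.082 and Prdm14 by 0.77 (adjusted p = 0.156 with an estimated correlation), and primitive endoderm genes were higher in 8 of 15 and lower in 1 (adjusted p = 0.18 with an estimated correlation).

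Among the genes higher at 2 h in knockout cells were Sec14l3 (8.54-fold), Sec14l5 (log2 fold change 2.26), the deubiquitinase gene Usp35 (202 ± 13 against 57.9 ± 5.4 CPM), Col4a1 (3.45-fold), Syt2 (3.30-fold), Otx2 (3.07-fold) and Lefty2 (3.02-fold). Lower were Rapgef4 (17.0-fold), Oaf (log2 fold change -3.59), Ccdc141 (6.02-fold), Duox1 (5.39-fold), Adgrg1 (4.68-fold), Emp1 (4.57-fold) and the integrin gene Itga7 (4.47-fold). edgeR called 1530 genes higher and 1820 lower (45.7% higher, 18.4% with library size alone). Among calls, 451 genes were lower at both 0 h and 2 h, where independent lists would share 175.

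At 8 h of 4OHT Nanog stood at 70.6 CPM in knockout and 19.8 CPM in rescued cells (log2 fold change 1.82 ± 0.10), Tbx3 was higher by 1.37, and naive genes were higher in 11 of 20 and lower in 3 (camera adjusted p 9.86e-06, adjusted p = 0.0723 with an estimated correlation). Feedback genes were lower in 16 of 21 and higher in 3 (adjusted p = 0.00316 with an estimated correlation), with Dusp5 at -1.61 and Spry4 at -1.14. Immediate early genes were lower in 19 of 28 and higher in 4 (adjusted over the list alone, 20 immediate early and 17 feedback genes were lower; adjusted p = 0.0831 with an estimated correlation), and Jun, higher at 2 h, was lower at -1.41 ± 0.11. Primitive endoderm genes were higher in 9 of 15 and lower in 2 (adjusted p = 0.425 with an estimated correlation), among the 9 Fgfr2, which belongs to the 13 abundant genes. Without the 3 high-share libraries 7 were higher.

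Lefty2 was 13.9-fold higher in knockout cells at 8 h (23.9 ± 2.5 against 1.80 ± 0.38 CPM), followed by Themis (6.81-fold), Hcrtr2 (5.00-fold), Rpl39l (4.17-fold), Fstl5 (3.87-fold), Atp1b2 (3.58-fold) and the cyclin gene Ccnd2 (3.56-fold). Ccdc107 was 4.61-fold higher but moved with Cdk8 between libraries of one group. Without the 3 high-share libraries, with only clone A left in the knockout 8 h group, its log2 fold change was 0.15. Lower were Rapgef4 (14.8-fold), Cyp26a1 (9.96-fold), Ociad2 (7.08-fold), the cadherin gene Cdh13 (6.90-fold), Duox1 (6.59-fold), Adgrg1 (6.31-fold) and Nptxr (6.28-fold). edgeR called 2049 genes higher and 2421 lower (45.8% higher, 8.17% with library size alone). At both 2 h and 8 h 1086 genes were lower, where independent lists would share 312, and 754 were higher, against 222.

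**Figure D2:**
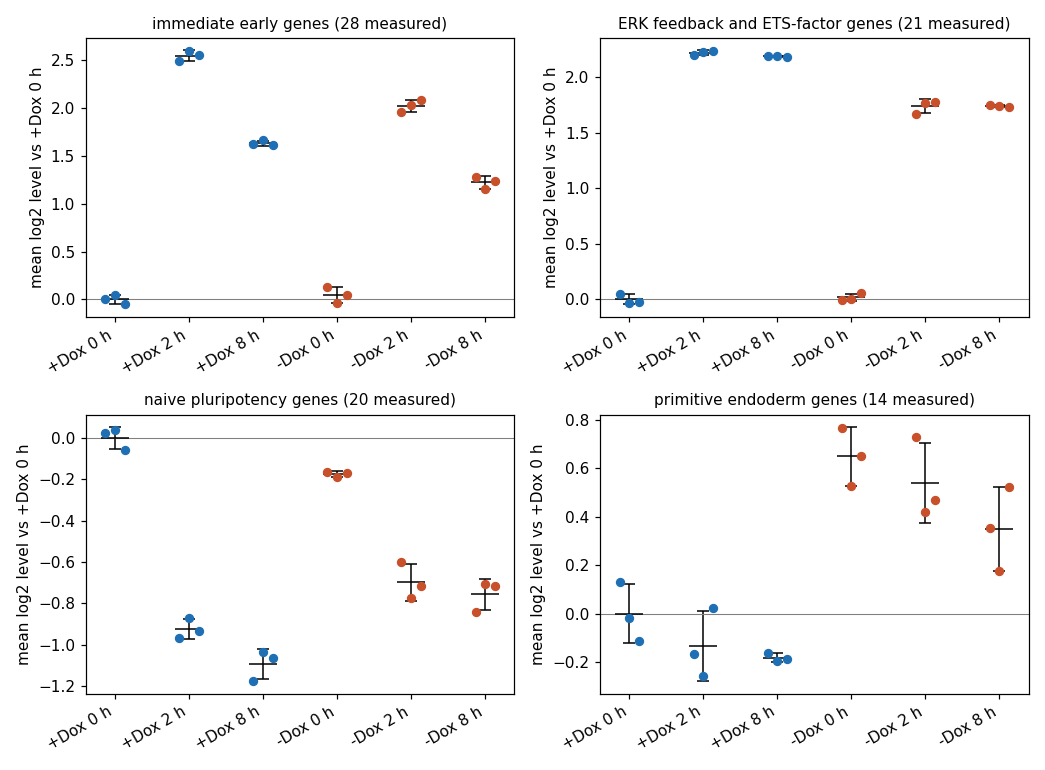
Mean log2 level of 4 gene lists per library, relative to the mean of rescued libraries at 0 h, with one point per library and mean ± SD of 3 libraries as bars; the primitive endoderm panel leaves out Fgfr2. Immediate early and feedback genes rise in both genotypes and stand lower in knockout libraries at 2 h and 8 h, and the naive list falls less in knockout libraries.

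Whether the response itself differed with Med24 was tested by interaction. For naive genes the 2 h log2 change in knockout cells minus that in rescued cells was above 0 in 12 of 20 genes and below it in 2, with Prdm14 at 1.11 and Nanog at 0.70 ± 0.11 (13 above 0 when adjusted over the list alone; camera adjusted p 6.96e-11, adjusted p = 0.0108 with an estimated correlation). A difference above 0 was not always a smaller fall: Klf4 fell in rescued cells but rose in knockout cells (99.1 to 123 CPM), and 8 of the 20 genes were already lower in knockout cells at 0 h. The 2 h rise of feedback genes was smaller in 9 of 21 and larger in 1, or 3 when adjusted over the list alone (adjusted p = 0.0324 with an estimated correlation). For trophectoderm genes the difference was below 0 in 5 of 10 (adjusted p = 0.016 with an estimated correlation). Their mean log2 level rose in rescued cells. In knockout clones A, B and C it went from 0.033, -0.133 and 0.033 at 0 h to -0.219, -0.464 and -0.059 at 2 h. For immediate early genes the 2 h rise was smaller in 15 of 28 (16 when adjusted over the list alone) and larger in 2, Jun (1.47 ± 0.13) and Egr1 (1.01 ± 0.16), with an adjusted p = 0.0723 with an estimated correlation. Egr1 started lower in knockout cells (log2 difference -1.44 at 0 h) and was still lower at 2 h (-0.43 ± 0.088). Its larger fold was thus not a higher level, whereas Jun was higher at 2 h by 1.57. Tead4 (chromosome 6, 128224288 to 128300823) rose from 55.8 to 310 CPM in rescued cells and stood at 78.1 and 82.2 CPM in knockout cells, a difference of -2.38 ± 0.097.

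Differences below 0 were also largest in Itga7 (-2.51 ± 0.43), Gsg1 (-2.42), Gpr142 (-2.39) and Phlda1 (-2.33 ± 0.23), and above 0 in Sec14l5 (2.78 ± 0.28), Hhip (2.26), Syt2 (2.15), Usp35 (1.89 ± 0.16) and Nptx1 (1.84 ± 0.54). The calls for Gsg1, Gpr142 and Nptx1 were each lost when single libraries were left out. For Nptx1 the adjusted P in edgeR was 0.082 without knockout 0 h clone A, 0.106 without rescued 0 h clone A and 0.0908 without rescued 0 h clone C. For Gpr142 it was 0.116 and 0.0703 without knockout 0 h clones B and C and 0.135 without rescued 0 h clone C. For Gsg1 it was 0.535 without knockout 0 h clone A, where the difference was -1.31, and between 0.05 and 0.105 without rescued 0 h clone B or C, knockout 2 h clone B or rescued 2 h clone B. For the 2 h interaction edgeR called 933 genes above and 933 below 0 (50% above, 9.68% with library size alone), of which 58 and 269 exceeded 2-fold.

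At 8 h the naive genes differed in 14 of 20 above 0 and 1 below (15 and 3 when adjusted over the list alone; camera adjusted p 7.57e-16, adjusted p = 0.00364 with an estimated correlation), with Nanog at 1.71 ± 0.13 and Prdm14 at 1.53. Feedback genes were below 0 in 12 of 21 and above in 3 (adjusted p = 0.016 with an estimated correlation). Lefty2 (3.57 ± 0.35), Aqp3 (2.78), Hhip (2.30) and Phlda2 (2.29) had the largest positive differences, along with Ccdc107 (2.50), whose difference was 0.44 without the 3 high-share libraries. Cyp26a1 (chromosome 19, 37697798 to 37701536; -3.33 ± 0.80), Aldh1a3 (-2.70 ± 0.95), Ociad2 (-2.69), the homeobox gene Msx1 (-2.42) and Fosl2 (-2.33 ± 0.21) had the largest negative ones. Aldh1a3 had an adjusted P of 0.0482 in edgeR, 0.0528 with the replicate block, and a range over alternatives of 0.0171 to 0.745; without knockout 0 h clone B its difference was -1.25. Leaving out knockout 0 h clone C, knockout 8 h clone B, rescued 0 h clone B or C or any rescued 8 h clone also ended the Aldh1a3 call, at adjusted P values from 0.054 to 0.0996. edgeR called 1113 genes above and 1254 below 0 (47% above, 6.15% with library size alone).

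The slope of knockout on rescued changes was below 1 at both times over genes called for the average response. At 2 h it was 0.832 over 10674 genes (jackknife SE 0.04), 0.775 for rising and 0.902 for falling genes. At 8 h it was 0.779 over 9780 genes (jackknife SE 0.035), 0.743 for rising and 0.824 for falling genes. Of the genes rising at 2 h that were called for the interaction, 629 rose less and 462 more in knockout cells. At 8 h the numbers were 789 and 320. The median difference was -0.011 at 2 h and -0.06 at 8 h on the log2 scale. The response was smaller in knockout cells for 51.4% of rising and 51.8% of falling genes at 2 h, and for 58.7% and 57.3% at 8 h.

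**Figure D3:**
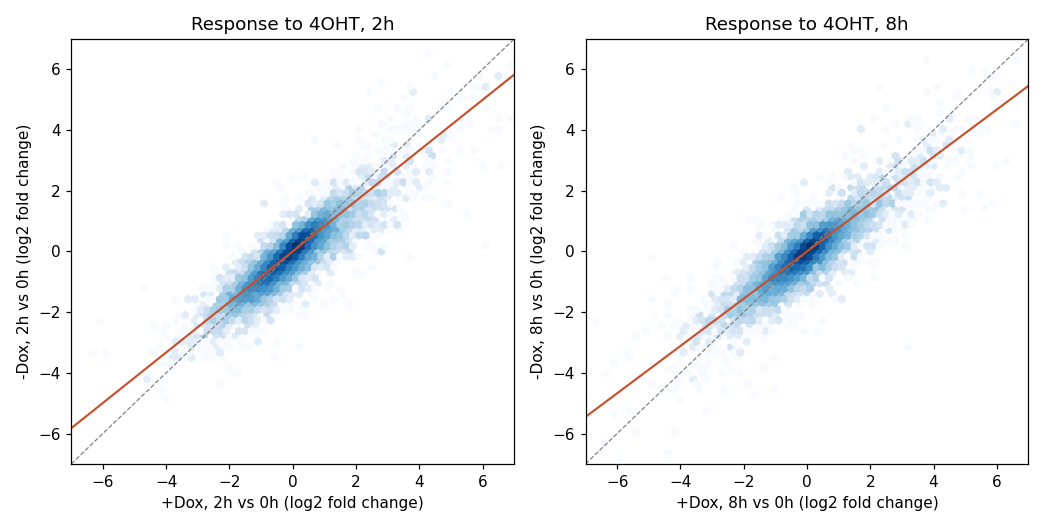
Log2 fold change against 0 h in knockout (vertical) and rescued cells (horizontal) at 2 h (left) and 8 h (right), over 14128 genes, with darker cells holding more genes on a log scale. The solid line has the fitted slope of 0.832 or 0.779 and the dashed line marks equal responses.

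The last comparison asked whether genes that ERK lowers are also lowered when Med24 is withdrawn. Across 14128 genes, which are not independent replicates, the rescued 2 h response had Pearson's r of 0.0845 and Spearman's rho of 0.0847 with the knockout difference at 0 h. The jackknife SE of r was 0.089, and r was 0.136 without rescued 0 h clone A and 0.169 without rescued 0 h clone C. Both comparisons share the rescued 0 h libraries, and unchanged groups simulated on them gave a Pearson's r of 0.52. The covariance was 0.0312 against 0.017 simulated, a difference of 0.0144, and 688 genes were lower in both where independent lists would share 461. In 20 simulations with no gene changed, at most 1 gene was called in both comparisons, in either direction. Genes changed in a single comparison were not simulated. With the knockout difference at 8 h, which shares no library, r was -0.190, rho -0.101 and the covariance -0.0968. There 1096 genes rose with ERK and were lower in knockout cells, where independent lists would share 784. Lower in both were 789, where independent lists would share 819. At 8 h ERK had been activated in both genotypes, so the knockout difference at 8 h also holds any difference in response. A smaller response in knockout cells, as in the 8 h slope of 0.779, can give a negative sign by itself. The 8 h values therefore do not decide whether genes that ERK lowers also fall when Med24 is withdrawn.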

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

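The tests on the share of rising genes with a larger knockout response, on Med24 and on the 13 abundant genes, and those without the 3 high-share libraries, were chosen after seeing the data, although the bounds for the slopes without these libraries were written before those slopes were seen.

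Responses to 4OHT that differed between knockout and rescued cells by the interaction test numbered 1866 genes at 2 h and 2367 at 8 h. At 2 h the log2 differences were 2.78 for Sec14l5, 2.26 for Hhip, 2.15 for Syt2, 1.89 for Usp35 and 1.84 for Nptx1, and -2.51 for Itga7, -2.42 for Gsg1, -2.39 for Gpr142, -2.38 for Tead4 and -2.33 for Phlda1. At 8 h they were 3.57 for Lefty2, 2.78 for Aqp3, 2.5 for Ccdc107, 2.3 for Hhip and 2.29 for Phlda2, and -3.33 for Cyp26a1, -2.7 for Aldh1a3, -2.69 for Ociad2, -2.42 for Msx1 and -2.33 for Fosl2. The Ccdc107 difference was 0.44 without the 3 high-share libraries, with only clone A left in the knockout 8 h group. Its adjusted p for the interaction ranged from 9.63e-165 to 0.793 over the alternatives. The calls for Nptx1, Gsg1, Gpr142 and Aldh1a3 were each lost when single libraries were left out. Among gene lists whose interaction held with an estimated correlation, the median log2 difference at 2 h was 0.54 for naive pluripotency, -0.27 for ERK feedback and -0.79 for trophectoderm genes. At 8 h it was 0.53 for naive pluripotency and -0.51 for ERK feedback genes.

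When genotype was exchanged among the libraries of 0 h and of the later time compared, with the third time left in its groups, 1 of 40 splits, the real one, called as many genes at 2 h (1866, highest other 1565) and 1 of 40 at 8 h (2367, highest other 1898). These splits mix the genotype difference within a time into the groups, so they do not test the interaction apart from it. In both of these highest others, 3 knockout libraries at the later time and 1 at 0 h changed places, which turns the later genotype difference round and so keeps most of it. An exchange of all libraries at a single time, which would keep the whole genotype difference, was not among those drawn. An exchange at all 3 times was also run and is not reported. No gene was called in 29 and 33 of the 39 others. In the test of the interaction itself, the highest adjusted p over the alternatives was 6.89e-15 for Tead4 and 2.07e-08 for Usp35 at 2 h and 8.21e-07 for Lefty2 at 8 h. Among the other genes named by size, it rose above 0.05 for Gsg1, Gpr142 and Nptx1 at 2 h and for Aldh1a3 and Ccdc107 at 8 h. All were picked as the largest differences, and the alternatives refit the same libraries. These values therefore do not decide how many calls arose by chance. For each comparison of 3 with 3 libraries only 10 splits exist, too few for a share under 0.05. There 1 split, the real one, gave 9354, 8748, 9414, 8170, 2324, 3350 and 4470 genes for rescued 2 h and 8 h, knockout 2 h and 8 h, and the knockout difference at 0, 2 and 8 h, and the highest other split gave 0 in each.

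The smaller response without Med24 was first set against the 3 knockout libraries in which 13 abundant genes hold a high share. Without them the slope was 0.850 at 2 h and 0.793 at 8 h, against 0.832 and 0.779 with them. At 2 h this argues against these libraries as the whole cause. At 8 h only clone A was then left in the knockout group. That value has no spread between clones and does not decide the question. A stimulus weaker by one factor for every gene cannot be told apart from other sources, because its test depends on the scaling. Of the rising genes called for the 2 h interaction, 42.3% had a larger knockout response with TMM, 47.6% with RLE scaling and 6.9% with library size alone. With TMM, 35.7% of those with a larger response were lower in knockout cells at 0 h. As a hypothesis, part of the response may depend on Med24, but doxycycline, given to rescued cells only, and unequal cRAF-ErT2 activity remain open.

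The rise of Med24 reads at 2 h in rescued cells was not removed by scaling, since the log2 fold change was 1.42 with library size alone. It was 0.251 in knockout cells, which argues against a response of the endogenous locus of that size; its call was lost without knockout 0 h clone C (0.195), 2 h clone A (0.217) or 2 h clone C (0.238). A response of the tetracycline-regulated cDNA itself to 4OHT is a candidate explanation that was not tested, because its reads were not counted apart.

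After TMM scaling, the level of each of the 13 abundant genes in the 3 high-share libraries was at least 1.9-fold that in the other libraries of the same knockout group. The genes were chosen for a spread and a correlation with Cdk8 within groups, so this difference between clones follows from the choice. It therefore does not test Med24 withdrawal as a source, although clones of one group were treated alike. Unlabelled stable RNA carried through the capture would raise ribosomal protein genes too. Their median ratio to the low-share libraries of the same group was 1.04, 1.15 and 1.28 in the 3 libraries, the lowest of them 1.04, so carry-over cannot be told apart from other sources with these counts. The rise in 3 of 6 knockout libraries after 4OHT and in no rescued library also leaves a part for genotype open.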

How the results depend on the processing

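The alternatives without the 3 high-share libraries, with the share of the 13 genes as a covariate and without genes following Cdk8 were chosen after seeing the data. The 9 counts of called genes stayed within 1.5 times of their values under RLE scaling, no filter, DESeq2, the replicate block, fits on only the groups compared, and the alternatives chosen after seeing the data. Leaving out single libraries gave 1598 to 1780 genes for the knockout difference at 0 h, 1418 to 1932 for the 2 h interaction and 1672 to 2449 for the 8 h interaction. The replicate block called 1831 genes for the 2 h interaction and changed the call of 1 named gene, Aldh1a3 at 8 h, and of 2 list tests. These were BMP and Nodal targets at 0 h (adjusted p 0.0393 without and 0.112 with it) and general pluripotency genes in the 8 h interaction (0.0495 and 0.0502). It changed no other call among these.

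With library size alone the knockout differences fell to 420 genes at 0 h and 1661 at 2 h, and the 2 h interaction to 589. This setting shifts the median of all genes by -0.158 (rescued 2 h), -0.284 (knockout 2 h), -0.359 (knockout 8 h), -0.254 (knockout difference at 8 h), -0.0709 (rescued 8 h), 0.0337 and -0.0917 (knockout difference at 0 h and 2 h), -0.125 and -0.289 (2 h and 8 h interactions). In the same setting Med24 in knockout cells turned from 0.25 to -0.035 at 2 h and from 0.03 to -0.33 at 8 h, and its 8 h interaction fell short of the threshold (0.18, adjusted p 0.544). The 2-fold threshold, by construction, left 2806 and 2507 genes in rescued and 2664 and 2096 in knockout cells at 2 h and 8 h, 166, 487 and 657 for the knockout difference at 0, 2 and 8 h, and 327 and 426 for the interactions. The 8 h slope was 0.817 over genes chosen on the knockout response. The correlation of the ERK response with the 8 h knockout difference was -0.231 over genes of at least 5 CPM and -0.101 by Spearman. The cause was not tested.

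With the share as covariate, Ccdc107 at 8 h turned to -0.090. Without the 3 libraries, camera directions turned for ribosomal protein (adjusted p 0.987) and histone genes (0.149) in the knockout difference at 8 h, and for general pluripotency genes in the 8 h interaction (0.987). Of 138 followed gene values, 9 changed their call in any setting. With an estimated correlation 56 list calls were lost. Depth and 3 libraries per group limit small changes. Of 1.25-fold simulated changes at 2 h in rescued cells 28% were recovered, in a simulation that changed far fewer genes than were called in the real data.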

Other observations

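The values without the 3 high-share libraries were chosen after seeing the data. At 8 h they rest on clone A as the only knockout library left. At 8 h in rescued cells 12 of 14 integrated stress response genes were higher and 1 lower, among them Asns (1.36 ± 0.094 on the log2 scale), Psat1 (1.41) and Vldlr (3.68), and in knockout cells the counts were the same, 12 and 1 (adjusted p = 0.592 and 0.38 with an estimated correlation). Ribosome biogenesis genes were higher in 21 of 22 in rescued and 22 of 22 in knockout cells at 8 h (adjusted p = 0.256 and 0.0536 with an estimated correlation). Cholesterol synthesis genes were lower in 9 of 19 (10 when adjusted over the list alone) in knockout against rescued cells at 8 h, with Msmo1 at -0.64 ± 0.062 (adjusted p = 0.667 with an estimated correlation). At 2 h 6 were higher and 2 lower (7 and 2 when adjusted over the list alone), and at 0 h 2 were higher with none called lower. BMP and Nodal targets moved apart at 2 h in knockout against rescued cells, 4 higher and 5 lower of 12: Nodal was higher by 1.27 ± 0.085 while Id1 was lower by -1.86 ± 0.081 and Smad7 by -0.83 (camera adjusted p 0.762).

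Of 2-cell-like genes, which mark a rare early-embryo-like state, only 3 were measured. At 8 h in knockout against rescued cells Zscan4d was higher by 3.42 ± 0.57 on the log2 scale. Usp17le was 43.0-fold higher (counting interval 7.12 to 1760) and Zscan4e 33.8-fold (5.47 to 1400), each with 1 count in rescued cells. These genes belong to families of near-identical copies and are uncertain (adjusted p = 0.156 with an estimated correlation).

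Other lists are given for knockout against rescued cells at 8 h. Mediator genes other than Med24 were higher in 6 of 31 and lower in 4, with Cdk8 among the 13 abundant genes (7 and 4 when adjusted over the list alone, camera adjusted p 0.294). Cell cycle genes were higher in 12 of 20 and lower in 2, and without the 3 high-share libraries in 6 and 3 (13 and 3 with all libraries when adjusted over the list alone; 0.0225, and adjusted p = 0.596 with an estimated correlation), and p53 targets higher in 5 of 17 and lower in 3 (0.639). Heat shock genes were higher in 3 of 10 with none called lower, and without the 3 libraries higher in 1 and lower in 3 (2 higher with all libraries when adjusted over the list alone, 0.486), and cytoskeletal MRTF and SRF targets higher in 3 of 11 and lower in 2, and without the 3 libraries in 1 and 4 (0.201). Wnt targets were lower in 4 of 9 (0.0996), gastrulation genes higher in 1 and lower in 4 of 9 (0.0909), neural genes lower in 3 of 4 (0.109) and fibroblast genes higher in 1 and lower in 1 of 6 (3 and 1 when adjusted over the list alone, 0.597). Formative genes were higher in 6 and lower in 5 of 15 (0.423), and general pluripotency genes higher in 9 and lower in 1 of 14 (9 and 2 when adjusted over the list alone; 0.000907, and adjusted p = 0.409 with an estimated correlation). Ribosomal protein genes were higher in 22 of 82 and lower in 1 (21 and 1 when adjusted over the list alone), and without the 3 high-share libraries higher in 2 and lower in 3.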
